A study of Mus musculus with 2 samples.

How the data were processed

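Hearts of mouse embryos at day 12.5 were dissociated with TrypLE and profiled with a 10X Genomics Chromium droplet kit, v2 per the labels. Whether cells were sorted for YFP and how many embryos were pooled are not given in the sources used here. The deposited values were counts of unique molecular identifiers (UMIs) per gene and barcode, made by the authors with Cell Ranger 3.0.2 per the file headers. The submitters' processing notes also name Seurat, without a version. The genome build and annotation are not given in the sources used here. Both gene tables listed the same 31053 genes, of which 99.6% had an identifier in GENCODE M21 (GRCm38), used here for positions. The matrices were not alike. The control matrix listed 6794880 barcodes, 542175 of them with a UMI, and so was unfiltered. The mutant matrix listed 7181 barcodes with at least 500 UMIs each, and so was already filtered. All 7181 were in the control's barcode list. The size of that list is that of the list distributed for a later version of the kit, so the chemistry is uncertain.

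The same minimums were applied to both libraries: 1000 UMIs, 500 genes and at most 20% of UMIs from mitochondrially encoded genes. They left 4100 control and 4640 mutant cells. A further 1744 control and 2131 mutant barcodes reached 1000 UMIs but not 500 genes and were left out. Doublets were scored per library after the Scrublet method, with an expected rate of 6% and 30 neighbours. Its automatic threshold marked 4 control and 17 mutant cells, too few to have worked. Clusters in which at least 50% of cells were among the top 6% of scores were therefore also removed, 147 control and 91 mutant cells, which left 3949 and 4532 cells.

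Counts were scaled to 10000 per cell and log-transformed. From 2000 variable genes, without Prmt1, mitochondrial, ribosomal, haemoglobin and sex-linked genes, 30 principal components were taken, and a graph of 15 neighbours was clustered with the Leiden method at resolution 1 (leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, scikit-image 0.26.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, Python 3.11.15). Both libraries were clustered together with no batch correction. A cluster took the name of the marker set with the highest mean score out of 11 sets fixed before the data were examined, each marker as log2(CPM/10 + 1) relative to its highest cluster. Clusters with under 3 markers detected in 10% of cells stayed unnamed, as did clusters with a median UMI count under 33.3% of that of their library and none of their markers among the 10 leading genes. The scoring and naming rules and the rule on doublet clusters were set with the data at hand. With each library clustered on its own, this rule on depth was not applied, except in 1 added alternative. The design named an epicardial-like class. Because mesenchymal markers outnumbered epicardial ones among the leading genes of clusters 3, 17 and 24, these are compared by number.

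UMIs, as deposited by the authors, were summed over the cells of each group and library and divided by the group's total (CPM). Gene ratios are log2((CPM mutant + 10)/(CPM control + 10)). For Prmt1 the plain ratio is given with an exact conditional binomial interval. Shares have exact Clopper-Pearson intervals and their differences Newcombe's intervals, and levels in the plot of Prmt1 have exact Poisson intervals, all at 95%. A count of 0 was read as allowing up to 3 UMIs. List medians use members with at least 10 CPM on average, and their intervals come from 1000 Poisson redraws. Each is placed among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries. Intervals cover counting error only, not differences between embryos. With 1 library per group no p-value, standard error or number of changed genes is given.

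Genes were named by a rule fixed before the data were examined. For epicardial, mesenchymal and cardiomyocyte groups, candidates had at least 50 CPM in 1 library and at least 30 UMIs over both, and were not mitochondrial, ribosomal, haemoglobin or sex-linked genes, Gm or Rik models or markers of another class. The 10 highest and 10 lowest were named among those whose endothelial log2 ratio was opposite in sign or under 50% as large, with up to 4 members of each list past 1.5-fold at the same minimums, the Prmt family, and genes past 2-fold in all 4 groups. Further list members whose values lay between are named as context and were chosen after their values were seen. There were 21 gene lists, also fixed beforehand; those on immediate early, sarcomere and extracellular matrix genes were followed through the alternatives after their values were seen. The ratio computation was tested on Poisson counts simulated with the totals and means of clusters 3, 17 and 24, with 200 of 2381 genes changed. All genes changed by 1.5-fold had the right direction, and the 95% intervals held the true ratio for 92.5% of them, 95.5% at 2-fold and 93.9% at 4-fold. The intervals themselves assume Poisson counts and the simulation held no spread between cells, so this checks the computation only. It cannot show that the intervals hold for real UMIs, which a few cells may supply.

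Alternatives changed 1 choice at a time, except separate clustering, which also left out the rule on depth: the UMI and mitochondrial limits, doublet removal, cluster resolution, separate clustering, TMM scaling (edgeR 4.0.16 in R 4.3.3), median-of-ratios scaling (DESeq2 1.42.0), thinning of cells to 2000 UMIs, equal weight per cell, the pseudocount and the filter on list members. No test of either package was run. Added after seeing the data were minimums of 500 UMIs and 200 genes, a mutant library thinned by the ratio that matched the median UMIs of clusters 3, 17 and 24, removal of the top 6% of doublet scores, clusters 3 and 5 alone, clusters 18 and 24 left out, separate clustering with each marker's maximum set to at least 100 CPM, and separate clustering with the rule on depth kept.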

Results

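Single-cell RNA profiles were measured in mouse hearts at E12.5, a stage of midgestation. The control carried Tbx18-Cre and a YFP reporter, and the mutant carried the same alleles together with floxed Prmt1 on both chromosomes. Tbx18-Cre recombines in the epicardium, the outer cell layer of the heart that gives rise to mesenchymal cells, and Prmt1 encodes the main asymmetric protein arginine methyltransferase. The series title calls the deletion epicardial-specific. There was 1 library per genotype, so no difference has a replicate check or a test, and each interval covers counting error only. After filtering, the control held 4100 cells with a median of 5897 UMIs and the mutant 4640 cells with a median of 4046 UMIs. The deposited counts summed to 49323576 UMIs in the control and 48527471 UMIs in the mutant.

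Joint clustering gave 26 clusters. Cardiomyocyte-like cells were the most numerous, in 8 clusters led by Myl2, Myl3, Myl7, Nppa and Ttn. Mesenchymal-like cells formed clusters 2 and 8, led by Msx1, Car3 and Cthrc1, cluster 5, with Tcf21 and Ptn among its leading genes, and the deeply covered cluster 18, led by Vim, Vcan, Col1a1 and Postn. Most of the class lay in clusters 2 and 8, with 426 and 146 of 840 control cells and 717 and 255 of 1362 mutant cells. Which mesenchymal-like cells descend from the epicardium was not examined, so values for the whole class are not values for epicardium-derived cells. The epicardial markers scored highest in clusters 3, 17 and 24, led by S100a6, Krt18 and Upk3b. Their 10 leading genes also held more mesenchymal than epicardial markers (Dcn, and in cluster 24 Col1a1 and Col1a2), so these clusters are compared by number and not as a named class. Cluster 24 weighs heavily in their summed counts. It gave 523166 of 1437124 control UMIs from 32 of 395 cells, and 909219 of 2758785 mutant UMIs from 45 of 698 cells. A share of 0.325 of its cells was among the top 6% of doublet scores. Cluster 18 weighs heavily in the mesenchymal-like sums. It gave 547821 of 2184580 control UMIs from 46 of 840 cells, and 1288603 of 4376777 mutant UMIs from 79 of 1362 cells. Among its cells the share with such scores was 0.208. Endothelial-like, erythroid-like, immune-like and megakaryocyte-like clusters were also found. Cluster 20, led by Cxcl12, Hotairm1, Eln and Fbln5, stayed unnamed.

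Prmt1, the targeted gene (ENSMUSG00000109324; chromosome 7, 44975989 to 44986568 in GRCm38) was lower in the mutant library in clusters 3, 17 and 24, at 379 against 439 CPM (UMIs scaled to the total of the cell group). That is 86.4% of the control level, with an exact 95% interval of 78.2% to 95.5% from 631 and 1046 UMIs. In the Tcf21-high cluster 5 it stood at 549 CPM in the mutant and 681 CPM in the control, or 80.5% (69.9% to 92.8%). It was 111% of control in cluster 2 (100.35% to 123%), 121% in cluster 8 (105% to 140%), 103% in cluster 17 (76.8% to 139%) and 74.7% in cluster 24 (61.1% to 91.3%). Over all mesenchymal-like cells it was 647 and 632 CPM, 102% of control (96.0% to 109%). It was 570 and 554 CPM in endothelial-like cells, which are not known as Tbx18-Cre descendants, and 724 and 608 CPM in cardiomyocyte-like cells, 119% of control (116.6% to 121%). Relative to endothelial-like cells, the log2 ratio in clusters 3, 17 and 24 differed by -0.25 (-0.42 to -0.05). With a UMI minimum set per library, which left 43 control and 65 mutant cells of these clusters, the log2 ratio was -0.55 instead of -0.21, and with equal weight per cell it was -0.076. The counts come from 3' tags. A tag outside the deleted part of the gene is still made after deletion, and the deleted exons are not given in the sources used here, so these levels check nothing about the loss of Prmt1.

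**Figure D1:**
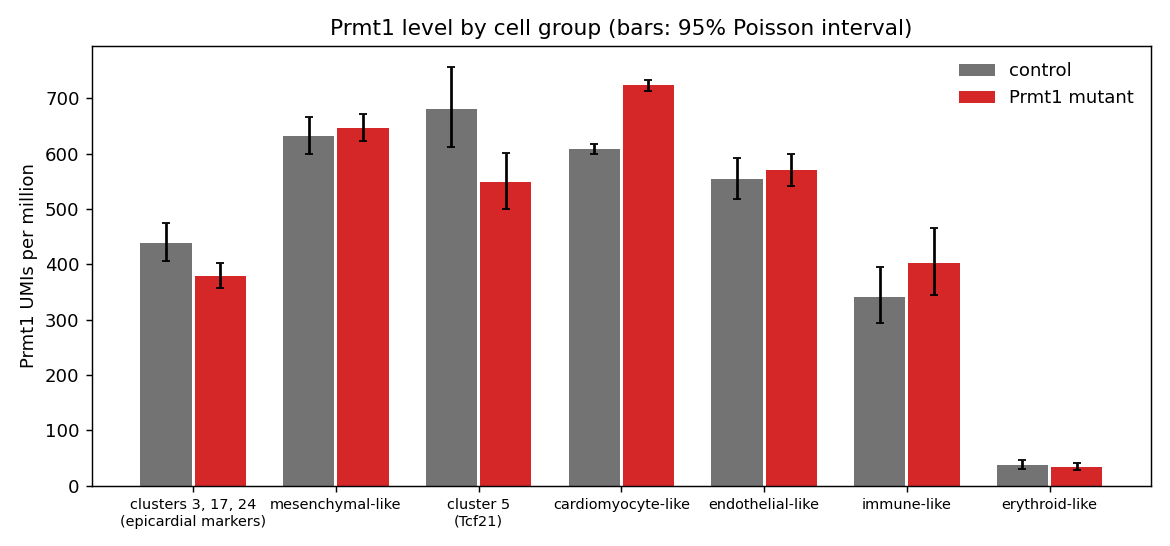
Prmt1 level in CPM (y axis) in each cell group (x axis) for the control library (grey) and the Prmt1 mutant library (red), 1 library each; error bars are exact 95% Poisson intervals. The mutant bar is lower in clusters 3, 17 and 24 (379 against 439) and in cluster 5 (549 against 681), and higher in cardiomyocyte-like cells (724 against 608).

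Other arginine methyltransferases were sparsely counted in clusters 3, 17 and 24. Carm1 stood at 19.9 CPM in the mutant and 28.5 CPM in the control, Prmt2 at 26.1 and 33.4 CPM, Prmt5 at 18.5 and 16.7 CPM, and Prmt7 at 10.9 and 15.3 CPM. Each rested on 22 to 72 UMIs per library. The other members of the family (Prmt3, Prmt6, Prmt8 and Prmt9) did not reach 10 CPM there. The median log2 ratio of the 5 measured members, which include Prmt1 itself, was -0.27 (-0.48 to -0.088), at percentile 4.58 of random lists matched on expression. In cardiomyocyte-like cells Prmt3 stood at 10.2 against 23.5 CPM, from 289 and 757 UMIs.

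Epicardial-marker and mesenchymal-like cells made up more of the mutant library. Clusters 3, 17 and 24 held 395 of 3949 kept control cells (10.0%, exact binomial 95% interval 9.08% to 10.98%) and 698 of 4532 mutant cells (15.4%, 14.4% to 16.5%), a difference of 5.40 percentage points (3.99 to 6.80, Newcombe). Mesenchymal-like cells made up 21.3% of the control (20.004% to 22.6%) and 30.1% of the mutant (28.7% to 31.4%), a difference of 8.78 points (6.93 to 10.6). Cardiomyocyte-like cells made up 52.1% of the control and 35.8% of the mutant. Endothelial-like cells were 7.07% and 8.25%, erythroid-like cells 4.94% and 7.48%, immune-like cells 2.28% and 1.85%, and the unnamed cluster 20 was 2.18% and 0.84%. Within the epicardial-marker and mesenchymal-like cells together, clusters 3, 17 and 24 took 32.0% in the control and 33.9% in the mutant, a difference of 1.90 points whose interval (-1.43 to 5.18) includes 0. It was -27.1 points with each library clustered on its own and the rule on depth kept, where 755 control and 300 mutant cells stayed unnamed. The epicardial-marker cells were shallow in both libraries, with a median of 2089 UMIs in the control and 2533 UMIs in the mutant, as were the mesenchymal-like cells (1865 and 2212 UMIs). The minimums of 1000 UMIs and 500 genes can therefore change these shares: with 500 UMIs and 200 genes the differences were 2.86 and 1.61 points. With a minimum per library they were 1.24 and 1.4996 points, but both shares were far smaller there. Epicardial-marker cells were 43 of 2088 control and 65 of 1970 mutant cells, and mesenchymal-like cells 45 and 72. These points are therefore not on the scale of the main ones. The labels do not say whether cells were sorted.

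**Figure D2:**
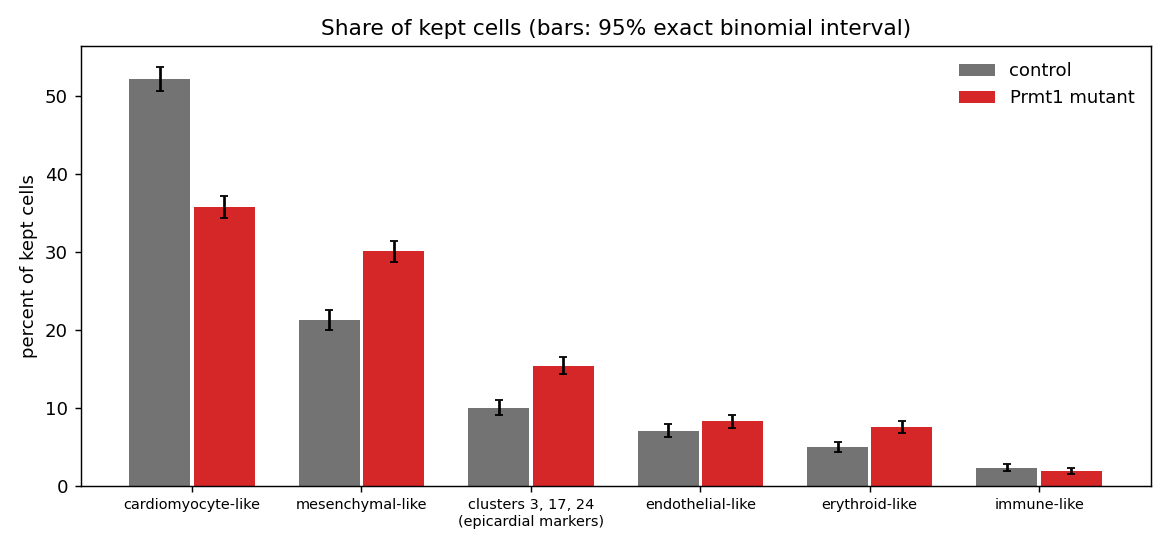
Share of kept cells in percent (y axis) for 6 cell groups (x axis) in the control library (grey) and the Prmt1 mutant library (red), 1 library each; error bars are exact 95% binomial intervals. Mesenchymal-like cells and clusters 3, 17 and 24 take larger shares of the mutant library, and cardiomyocyte-like cells a smaller one (35.8% against 52.1%).

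Genes are named where the ratio in endothelial-like cells was opposite in sign or under 50% as large. In clusters 3, 17 and 24, the gene with the highest ratio was Cited1, a transcriptional coactivator, at 88.4 CPM in the mutant and 14.6 CPM in the control. In cluster 3 alone its log2 ratio was -0.13, and in cardiomyocyte-like cells of the control it stood at 410 CPM. Next were Gsta4, a glutathione transferase (230 and 128 CPM), Strbp (66.7 and 40.4), Cir1 (51.1 and 30.6), Fam213b (120 and 76.5), Trim27 (53.3 and 32.7), Bgn, the proteoglycan biglycan (77.2 and 50.1), Ralgps2 (89.2 and 58.5), Socs2 (97.51 and 64.7) and Hist1h1a (58.4 and 37.6). Lower in the mutant library were Mgp, which encodes matrix Gla protein and is a leading gene of cluster 20 (204 against 694 CPM), Tmem37 (31.2 against 120) and the stress-induced transcription factor Atf3 (128 against 307). The 7 others among the lowest were Cnn1, Tnni2, Fbxl22, Cox6a2, Csrp3, Atp2a2 and Sh3bgr. With each library clustered on its own the log2 ratio of these 7 was above 0, from 0.088 for Cnn1 to 1.25 for Cox6a2, and that of Tnni2 was also above 0 in 5 other settings. All of these were higher in cardiomyocyte-like cells of the control than in these clusters, for example Csrp3 with 1667 CPM there against 88.4 CPM in the control clusters and 27.9 CPM in the mutant ones. Haemoglobin took 3.58% of UMIs in these clusters of the control and 5.19% in the mutant. In endothelial-like cells the log2 ratio of Mgp was -0.84 and that of Atf3 was -0.23.

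The p53 pathway was compared because it has been studied with Prmt1 in the epicardium. In clusters 3, 17 and 24, 11 of its listed target genes were measured, and their median log2 ratio was 0.056 (95% interval -0.12 to 0.23). This was percentile 88.5 of 10000 random lists matched on expression. Under the alternatives the median ranged from -0.081, with a UMI minimum per library, to 0.30 over 9 genes, with each library clustered on its own. The same genes had a median of 0.14 in endothelial-like cells. A single member passed 1.5-fold, the antiproliferative gene Btg2, which was lower at 34.1 against 66.8 CPM. Mdm2, the ubiquitin ligase that p53 induces, stood at 15.6 and 14.6 CPM, Bax at 173 and 179 CPM, Phlda3 at 80.8 and 73.1 CPM and Ccng1 at 11.2 and 14.6 CPM. The list of p53 regulators had a median of -0.0055, with Mdm4 at 26.1 and 19.5 CPM and Trp53 itself at 44.2 and 47.3 CPM.

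The 16 measured genes of the mesenchymal transition list had a median log2 ratio of -0.15 (-0.24 to -0.029) in the same clusters, percentile 3.92 of random lists. Twist1 (59.8 against 34.8 CPM, with a log2 ratio of 0.58 in endothelial-like cells as well) and Vim (1199 against 946) were higher in the mutant library. Acta2 (141 against 622), Itga5 (7.61 against 20.9) and Lox (16.7 against 32.0) were lower. Acta2 reached 8511 CPM in cardiomyocyte-like cells of the control. The median turned to 0.23 when each library was clustered on its own. Of the epicardial regulators, Tcf21, a factor of the fibroblast lineage, stood at 564 CPM in the mutant and 415 CPM in the control, Wt1 at 86.6 and 97.4, Tbx18 at 79.0 and 87.7, and Aldh1a2, which makes retinoic acid, at 148 and 184. The median of their list was -0.067 (percentile 29.4), and -0.24 (-0.44 to -0.042, percentile 0.59) in cluster 3 alone.

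The G2/M phase list of 33 measured genes had a median of -0.015 (-0.092 to 0.065) in clusters 3, 17 and 24, at percentile 64.2, with Tpx2 at 60.2 against 32.7 CPM. The S phase list of 25 had 0.052 (percentile 95.2), with Rfc2 at 54.4 against 90.5 CPM. The G2/M median was -0.23 with each cell thinned to 2000 UMIs and 0.34 when each library was clustered on its own. The 28 RNA-binding proteins known to carry methylarginine had a median of 0.063 (percentile 99.3), with no member past 1.5-fold. Their list also ranked high in mesenchymal- (99.89), cardiomyocyte- (99.99) and endothelial-like cells (100), so this rank is not particular to clusters 3, 17 and 24. The immediate early and dissociation list stood apart at -0.46 (-0.63 to -0.28), below all random lists, and 10 of its 22 measured members were lower by 1.5-fold or more. They included Atf3, Egr1 (89.9 against 199 CPM), Fos (176 against 342 CPM) and Ier2 (387 against 715 CPM). The sarcomere list had a median of -0.73, with Myh6 (19.6 against 160 CPM) and Ttn (89.5 against 394) lower. Nppa, of the trabecular myocardium list, was lower too (12.7 against 143 CPM), as it was in endothelial-like cells (14.4 against 95.5 CPM). Epicardial cells are not known to make these muscle transcripts, and the sarcomere median of 20 measured genes was -0.10 for 14 of them in cluster 3 alone, -0.26 for 11 in cluster 17, -0.79 for all 20 in cluster 24, and 0.038 for 13 of them without the top 6% of doublet scores. Over the same 20 genes the values for cluster 3 and without those scores were both -0.10, and that for cluster 17 was 0. When each library was clustered on its own, the sarcomere median turned to 1.08, over 13 genes, and the immediate early median to 0.13.

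Apart from trabecular myocardium, the other lists lay between percentiles 7 and 94.9 in clusters 3, 17 and 24. Their medians were -0.085 for epithelial genes, with Msln at 39.1 against 66.1 CPM, -0.12 for the extracellular matrix, with Lum at 64.5 against 37.6 CPM, -0.020 for TGF-beta and BMP, and -0.060 for FGF, PDGF, Hedgehog and Wnt. They were -0.018 for apoptosis, -0.11 for hypoxia and glycolysis, -0.093 for the unfolded protein response, 0.14 for the interferon response, -0.096 for compact myocardium and -0.11 for oxidative phosphorylation. The trabecular myocardium list, with 3 measured genes that include Nppa and Cited1, had -0.48 (percentile 0.84).

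**Figure D3:**
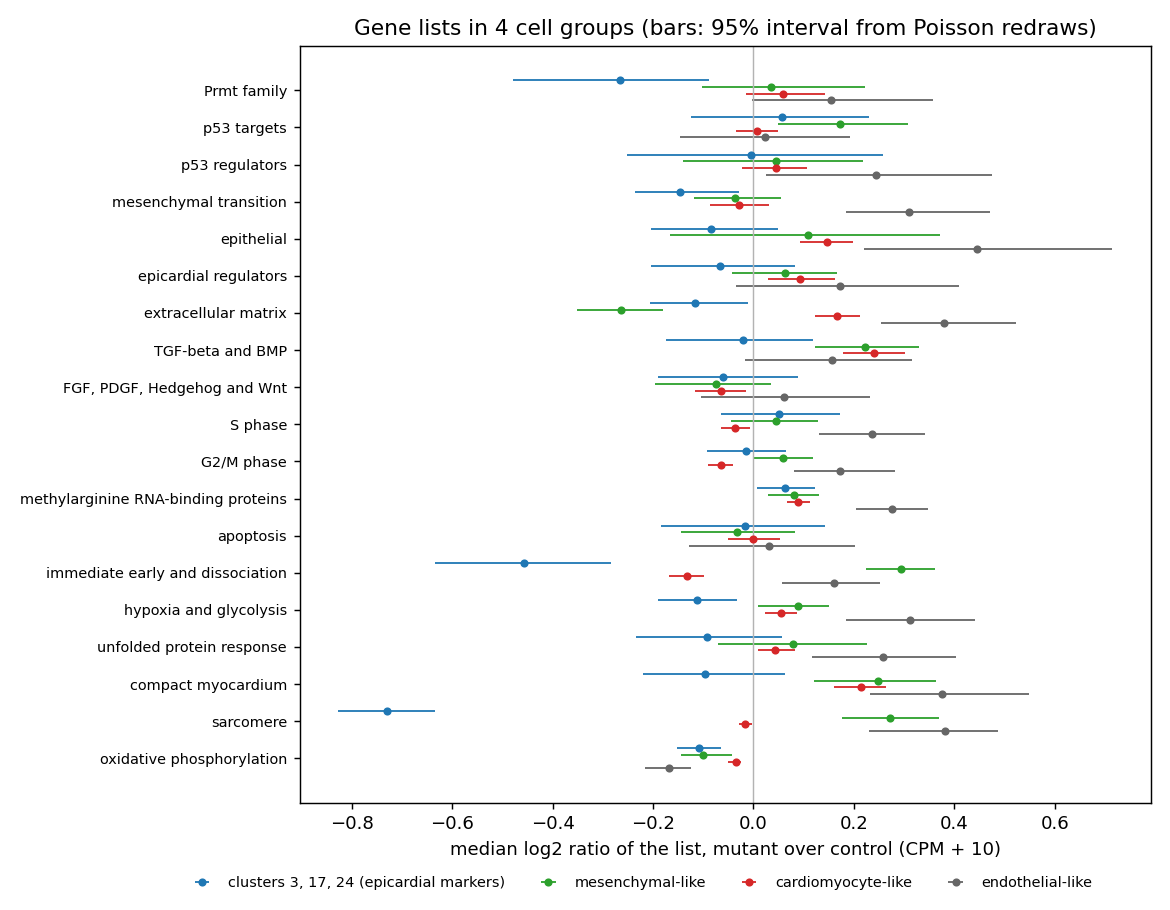
Median log2 ratio of mutant over control CPM plus 10 (x axis) for each gene list with at least 3 measured genes in all 4 groups (y axis) in clusters 3, 17 and 24 and in mesenchymal-, cardiomyocyte- and endothelial-like cells, 1 library per genotype; bars are 95% intervals from Poisson redraws of the counts. The immediate early list lies at -0.46 in clusters 3, 17 and 24 and at 0.29 in mesenchymal-like cells, and the p53 target list lies at 0.056 and 0.17 in the same groups.

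Summed over all mesenchymal-like cells, the mutant library had less RNA for several matrix proteins. The mean level of the mesenchymal markers was lower as well (212 against 257 CPM), as was that of the marker set for mural cells (214 against 298 CPM). The extracellular matrix list of 29 measured genes had a median log2 ratio of -0.26 (-0.35 to -0.18), below all random lists, against 0.37 for its genes in endothelial-like cells, where the mean level of the mesenchymal markers was itself higher in the mutant (32.6 against 17.8 CPM). Fbln5 (15.3 against 90.6 CPM) and Eln (28.6 against 101), which form elastic fibres, Col1a2 (193 against 359) and Dcn (103 against 184) were among the lower members. Also lower were the chemokine Cxcl12 (13.0 against 92.5), the Wnt-binding protein Sfrp2 (47.8 against 121), Dbi, a leading gene of cluster 2 (1441 against 3931), Dlk1 (33.6 against 76.4), Ltbp3 (23.99 against 52.2), Fabp3 (261 against 483) and Il11ra1 (23.3 against 107). Il11ra1 shares sequence with the gene model Gm13305, which stood at 66.5 against 0.916 CPM, so its counts are uncertain. Dbi and Il11ra1 were lower in endothelial-like cells too, with log2 ratios of -0.64 and -0.90. Cxcl12, Eln, Fbln5 and Sfrp2 were also leading genes of the unnamed cluster 20, which made up 2.18% of the control and 0.84% of the mutant. With each library clustered on its own, Cxcl12 and Fbln5 had log2 ratios of 1.25 and 0.048. With the rule on depth kept there, Eln and Fabp3 had 0.022 and 0.17. In cluster 5 alone the extracellular matrix median was -0.19 over 25 genes (percentile 0.27), and its interval (-0.39 to 0.014) included 0.

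Higher in mesenchymal-like cells of the mutant library were the transcription factors Klf2 (629 against 262 CPM) and Klf6 (334 against 179), the NF-kappa-B inhibitor Nfkbia (101 against 43.0), Atf3 (173 against 101), the heat shock genes Hspa1a (68.8 against 2.29) and Hspb1 (183 against 115), Fabp5 (424 against 246), Ppp1r14c (127 against 54.9) and Msx1 (530 against 343), a leading gene of clusters 2 and 8. Klf2 and Fabp5 also led the endothelial-like cluster 6. In endothelial-like cells Hspa1a was higher as well (66.5 against 20.5 CPM), and the log2 ratio of Ppp1r14c was 0.54. Hspb1 stood at 2555 CPM in cardiomyocyte-like cells of the control. Hsd3b6 stood at 64.7 CPM and had no UMI in the control, which allows up to 1.37 CPM. It is a leading gene of the erythroid-like cluster 10, and haemoglobin took 4.40% of UMIs in mesenchymal-like cells of the mutant and 1.53% in the control. The immediate early and dissociation list had a median of 0.29 (0.22 to 0.36) here. It was -0.12 in cluster 5 alone, where Hspa1a, Atf3 and Hspb1 were also not higher (-0.26, -0.062 and -0.67). The sarcomere list of 14 genes had a median of 0.27 (0.18 to 0.37) here, above all random lists, with Myh7 at 84.1 against 13.7 CPM. That median was 1.88 in cluster 18, but -0.081, -0.63 and -0.17 in clusters 2, 5 and 8.

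The 17 measured p53 targets had a median of 0.17 (0.048 to 0.31) in mesenchymal-like cells, percentile 99.7 of random lists, against 0.015 for the same genes in endothelial-like cells. Bbc3, which promotes apoptosis, was the member past 1.5-fold (16.2 against 6.87 CPM, from 71 and 15 UMIs). Plk2 stood at 98.5 and 62.7 CPM, Cdkn1a at 17.4 and 12.4, Mdm2 at 20.8 and 14.7, and Bax at 297 and 308. The median was -0.037 over 11 genes when each cell had equal weight, and -0.026 over 12 genes with each cell thinned to 2000 UMIs, which left out 472 control and 549 mutant cells. With separate clustering and the rule on depth kept it was -0.063, and in cluster 5 alone it was 0.011 over 8 genes (percentile 49.1). The TGF-beta and BMP list of 16 genes had a median of 0.22 (percentile 99.97), with Id2 at 390 against 254 CPM. The immediate early, sarcomere, compact myocardium (99.94) and methylarginine (99.89) lists also ranked above the p53 targets here, while the extracellular matrix list lay below all random lists. The percentile therefore does not set the p53 targets apart.

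In cardiomyocyte-like cells the log2 ratios of all measured genes had an SD of 0.14, against 0.29 in clusters 3, 17 and 24, and 32181651 control UMIs stood behind them. Lower in the mutant library were the muscle creatine kinase Ckm (183 against 375 CPM), Tnnt1, the slow skeletal troponin T (321 against 621), Cox8b (35.3 against 57.6), Spint2 (101 against 142), Hint2 (95.1 against 132), Igfbp5 (47.5 against 64.9), Itm2a (94.5 against 126), Syngr1 (47.0 against 63.9), Mtfr1l (75.4 against 100.2) and Stard10 (99.3 against 130). Higher were Fabp5 (274 against 165), Dap (61.8 against 42.3), Ddah1 (50.6 against 34.8), Mt3 (98.8 against 71.1), the natriuretic peptide gene Nppb (144 against 106), Med29 (197 against 147), Gsta4 (87.7 against 66.2), Apopt1 (103 against 78.3), Tagln2 (78.7 against 59.8) and Hebp1 (81.6 against 62.6). The sarcomere list had a median of -0.018, the trabecular myocardium list of 5 genes 0.25 and the compact myocardium list of 6 genes 0.21. The TGF-beta and BMP list had 0.24, the immediate early and dissociation list -0.13, the G2/M phase list -0.065 and the S phase list -0.036. The 10 measured p53 targets had a median of 0.0072.

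Endothelial-like cells were the group set beside the others. Their mean level of epicardial markers was 7.39 CPM in the mutant and 0.686 CPM in the control. With 10 CPM added to each level, no gene was lower by 2-fold or more in all of clusters 3, 17 and 24, mesenchymal-, cardiomyocyte- and endothelial-like cells, and 4 were higher. They were the gene model Gm10320 (293 against 0.641 CPM in endothelial-like cells), Gm13305 (65.3 against 2.56), Xist, which is made in female cells, and Pttg1, which encodes securin (282 against 127). In plain CPM, Pop4 and Il11ra1 were lower by over 2-fold in all 4 groups, Pop4 with 25.01 against 72.4 CPM in clusters 3, 17 and 24 and 37.8 against 99.9 CPM in endothelial-like cells; both were picked out after their values were seen. In cardiomyocyte-like cells Xist stood at 50.8 CPM in the mutant and 18.6 CPM in the control, and the Y-linked Ddx3y at 4.81 and 9.17 CPM. In mesenchymal-like cells the difference was larger, with Xist at 156 and 12.4 CPM and Ddx3y at 7.31 and 20.1 CPM. These levels go with a larger share of female cells in the mutant library. With 1 library each, a difference in the sex of the embryos cannot be told apart from the genotype. In endothelial-like cells the extracellular matrix list had a median of 0.38 and the methylarginine list 0.27, both above all random lists. Median-of-ratios scaling moved the log2 ratios there by -0.13.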

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

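All values in this part were picked out after they were seen, and none of the differences between cell groups was tested, since each genotype had 1 library. The Prmt1 ratio between the libraries went opposite ways in different cells: the log2 ratio was -0.21 in clusters 3, 17 and 24 and 0.25 in cardiomyocyte-like cells. The immediate early and dissociation list did the same, with a median of -0.46 in clusters 3, 17 and 24 and 0.29 in mesenchymal-like cells, but these turned to 0.13 with each library clustered on its own and to -0.12 in cluster 5 alone. A signal also appeared in barcodes that entered no comparison. Among barcodes with at least 1000 UMIs but under 500 genes, haemoglobin took a median of 73.3% of UMIs in the control and 65.1% in the mutant. In the control's 535027 barcodes under 100 UMIs, haemoglobin took 7.40% of 1560353 UMIs. The mutant matrix held no barcodes of that kind.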

How the results depend on the processing

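Of 130 alternative values of the compared results, 103 stayed within the counting interval of the value reported; the rest follow. The settings with minimums of 500 UMIs and 200 genes, a thinned mutant library, the top 6% of doublet scores removed, clusters 3 and 5 alone, clusters 18 and 24 left out, floored marker scores and the rule on depth kept in separate clustering were chosen after seeing the data. The cause was not tested for any of them. Thinning to 2000 UMIs left out 185 of 395 control and 183 of 698 mutant epicardial-marker cells. Both share differences stayed above 0 in all 12 alternatives each. The epicardial one (5.40 points) became 7.01 with at least 2000 UMIs and 2.86 with 500 UMIs and 200 genes. It was 1.24 with a minimum per library (5643 and 5667 UMIs), where such cells were only 43 of 2088 control and 65 of 1970 mutant cells. The mesenchymal one (8.78 points) became 1.4996 under the minimum per library, 1.61 (-0.0026 to 3.21) with 500 UMIs and 200 genes, 5.85 with the mutant library thinned to match the median of the epicardial-marker clusters, where 227 control and 321 mutant cells were unnamed, and 13.4 with separate clustering and floored scores, where 250 control cells and no mutant cells were unnamed. Prmt1 stayed lower in the mutant in all 17 alternatives, from -0.55 under the minimum per library to -0.076 with equal weight per cell. The p53 target median in mesenchymal-like cells turned to -0.026 with cells thinned and -0.037 with equal weight per cell, and was 0.011 in cluster 5 alone. In the epicardial-marker clusters, the mesenchymal transition median was -0.021 with equal weight per cell and -0.016 with 500 UMIs and 200 genes. The G2/M median was -0.23 with cells thinned, -0.16 in cluster 3 alone, -0.13 with at least 2000 UMIs, -0.16 with 500 UMIs and 200 genes and -0.19 without the top doublet scores. With each library clustered on its own and the rule on depth left out, where 120 control and 49 mutant cells fell in doublet clusters, the p53 target median was 0.30, mesenchymal transition 0.23, G2/M 0.34, immediate early 0.13 and sarcomere 1.08 in the clusters where epicardial markers scored highest. Cnn1 was 0.088, Tnni2 0.40, Fbxl22 0.30, Cox6a2 1.25, Csrp3 0.18, Atp2a2 0.21 and Sh3bgr 0.72, and in mesenchymal-like cells Cxcl12 1.25 and Fbln5 0.048. With that rule kept, which left 755 control and 300 mutant cells unnamed, the values for epicardial-marker cells were the same. The mesenchymal share difference was then 19.5 points, the share of epicardial-marker cells among both kinds differed by -27.1 points instead of 1.90, the mesenchymal p53 target median was -0.063, Cxcl12 1.62, Eln 0.022 and Fabp3 0.17. Tnni2 also turned in cluster 3 alone (0.21), without clusters 18 and 24 (0.46), at resolution 0.5 (0.45), with 500 UMIs and 200 genes (0.49) and without the top doublet scores (0.15), where Fbxl22 was 0.38 and the sarcomere median 0.038. In clusters 3 and 5 alone, Cited1 was -0.13, Hspa1a -0.26, Atf3 -0.062, Hspb1 -0.67 and the mesenchymal immediate early median -0.12. Under the minimum per library Fam213b was -0.037 and Hspb1 -1.01. No paired analysis was possible because each group held 1 library. Of the 1116 further values, for named genes and 4 more lists, 895 stayed within the interval, 184 moved and 37 changed sign.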

Other observations

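The tests in this part were chosen after the result they weigh was seen, except those on the deletion as the cause of the shares and on the genes around Prmt1; Bcl2l12 had been seen before the latter. Deep and shallow cells of the same kind stood side by side in both libraries. Clusters 18 and 24 had medians of 10078 and 11700 UMIs in the control and 14115 and 16262 UMIs in the mutant. Control cells of clusters 2, 3, 5, 8 and 17 had medians of 1559 to 3235 UMIs. Haemoglobin took 5.51% and 8.79% of the UMIs of clusters 18 and 24 in the control and 14.7% and 14.5% in the mutant, and at most 1.76% in the 5 shallower clusters of either library. In endothelial-like cells of the mutant, mesenchymal genes were higher, with Col1a1 at 60.0 against 6.41 CPM, Dcn at 52.5 against 14.1 CPM and Tcf21 at 66.8 against 21.1 CPM.

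Clusters 3, 17 and 24 and mesenchymal-like cells took larger shares of the mutant library. The tables argue against deeper cells of clusters 3, 17 and 24 in the mutant as the whole cause of their difference: it was 5.55 points with the mutant library thinned to 0.825 of its UMIs, which matched the median of these clusters alone, and 5.40 before, while the mesenchymal difference went from 8.78 to 5.85. A lower recovery of cardiomyocytes stays open: the ratio of epicardial-marker to endothelial-like cells was 1.32 times that of the control (1.08 to 1.61), 1.25 to 1.48 times in 11 alternatives and 0.880 times under the UMI minimum per library, and that of mesenchymal-, erythroid- and immune-like cells was 1.21 (1.01 to 1.45), 1.30 (1.02 to 1.65) and 0.696 (0.495 to 0.974) times, but with 1 library each these intervals cover counting error only. The UMI and gene minimums also stay open, with a difference of 2.86 points at 500 UMIs and 200 genes. So does the Prmt1 deletion, because with 1 library per genotype the genotype, the embryos and their dissociation cannot be told apart.

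Heart muscle transcripts were lower over clusters 3, 17 and 24 of the mutant together, with a sarcomere median of -0.73 (1.08 with each library clustered on its own). Cluster 24 stood at -0.79 and cluster 3 at -0.10 (-0.30 to 0.018). Cluster 17 stood at -0.26 (-0.64 to 0.10) over 11 genes, but at 0 over the same 20 genes as cluster 24. Less free muscle RNA in all mutant droplets as the whole cause is argued against by cluster 3 and by the median of 0.38 (0.23 to 0.49) in endothelial-like cells. Of the 18 genes behind the latter, 5 were higher by 1.5-fold or more and 3 lower: Myh6 (log2 ratio -0.77), Myl4 (-0.59) and Myl9 (-0.68). Endothelial-like cells of the mutant also held more epicardial and mesenchymal marker RNA, so they are an imperfect gauge of free RNA. The mean level of the cardiomyocyte markers was 118 against 2443 CPM in immune-like cells, from 84 mutant and 90 control cells. It was 244 against 209 CPM in endothelial-like cells and 85.1 against 66.8 CPM in mesenchymal-like cells. How many cells carried the immune-like difference was not examined, so a loss of free muscle RNA stays open for that group. The sarcomere median was also -0.081 and -0.17 in clusters 2 and 8 and 1.88 in cluster 18. It was -0.63 over 12 genes, or -0.30 over the same 20 genes, in cluster 5, so a smaller loss stays open. The pattern is consistent with muscle RNA in a few cells that may be doublets, since the median was 0.038 over 13 genes, or -0.10 over the same 20 genes, without the top 6% of doublet scores. In cluster 3, 5 control cells held 29.7% of the sarcomere UMIs and 5 mutant cells 8.35%, but in cluster 24 the top 5 cells held 73.5% and 74.2%. No biological explanation was tested.

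Some genes differed in endothelial-like cells as well. Reads of Il11ra1 placed on its near copy are a candidate explanation for Il11ra1 and Gm13305, which share 66.2% of the 31-base words of Gm13305: in 4 of 4 groups the sum of both genes differed by less than 50% of the log2 ratio of Il11ra1. The plain log2 ratio of Il11ra1 in endothelial-like cells, -1.06 (-1.45 to -0.68), belongs to the pattern itself and so leaves the place of the Prmt1 deletion open. Il11ra1 and Gm13305 lie on chromosome 4, Pttg1 on 11, Gm10320 on 13 and Xist on X, while Prmt1 lies on 7. These positions argue against other DNA around the Prmt1 locus as a direct cause for those genes. Such DNA stays open for genes on chromosome 7. The 21 genes within 5 Mb of Prmt1 reached percentile 83.2 of random sets, but the limit of 95 set beforehand could not exclude it. Their median absolute log2 ratio of 0.14 lay within the random range of 0.071 to 0.17. On chromosome 7, Bcl2l12, 0.015 Mb from Prmt1 (25.7 against 68.5 CPM in endothelial-like cells), and Pop4, at -6.71 Mb and outside that window (37.8 against 99.9 CPM), were lower in the mutant.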
